A study of Mus musculus with 6 samples.

How the data were processed

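Liver RNA of 6-week-old mice of the C57BL x 129S6/SvEv background was sequenced on the Illumina GAIIx with reads of 54 bases. The 6 libraries comprise 3 from wild type mice and 3 from Atp7b-/- mice, which lack the copper-transporting ATPase that is mutated in Wilson disease. All mice ate a diet with 16 ppm copper, per the labels. Total RNA was extracted with Trizol and cleaned on RNeasy columns, per the labels' protocols. Wild type replicate 1 and Atp7b-/- replicate 3 were sequenced paired-end and the other 4 libraries single-end. By the labels, wild type replicate 1 and Atp7b-/- replicates 1 and 2 are male, and wild type replicates 2 and 3 and Atp7b-/- replicate 3 are female. Replicate numbers follow the order of deposition and pair no samples. The labels do not say in so many words that each library came from a separate animal. The p-values therefore measure the spread between these libraries, which may include technical spread.

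The authors deposited 1 table of raw counts per Ensembl gene, with 1 column for each library and no normalization. Per the submitters' processing notes, the tools were STAR 2.4, featureCounts without a stated version and edgeR 3.8, and the genome build was GRCm38. The annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here. It is also not given whether a read pair counts as 1 or as 2 in the paired-end libraries. Genes of near-identical families (the Mup, Mug, Gsta, Acot, Cyp2c and Serpina1 genes, Clec2h and Itln1) and overlapping or antisense genes are therefore uncertain as single genes. The authors' deposited counts were read as whole numbers with 41388 gene identifiers, none of which was a summary line, and 16258 of them had a count of 0 in every library. Gene symbols and coordinates came from a GENCODE annotation of build GRCm38, which named 40254 identifiers and left 1134 without a symbol. A table of differential expression that the labels mention was not used here.

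Total counts were 23651080, 12258024 and 5919389 in wild type replicates 1 to 3 and 16597683, 6746192 and 25973968 in Atp7b-/- replicates 1 to 3. For the paired-end libraries these are 65% and 67.7% of the 36360686 and 38366743 reads stated in the labels. The 10 most abundant genes took 16.2% to 22.1% of the counts. The share of mitochondrially encoded genes was 7.74% and 8.14% in the paired-end libraries and 2.5% to 4.15% in the single-end ones. TMM factors lay between 0.9124 and 1.122. No pair of libraries agreed within sampling noise (chi-square per gene 33.9 to 448), so none was merged with another; this does not show that they came from separate animals. The first principal component of the log2 CPM values (65% of the variance) separated the layouts, and the second (16.9%) the genotypes.

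Differential expression was tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, the edgeR expression filter with a minimum count of 10, a robust quasi-likelihood fit with layout and genotype as terms, and Benjamini-Hochberg adjustment over the 12988 genes that passed the filter. A gene was called at an adjusted p under 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. Layout was chosen as covariate because it is the known sequencing batch and holds both genotypes. Within each layout the labelled sex follows the genotype completely, in opposite directions, so that layout equals the interaction of genotype and labelled sex. The difference between labelled sexes was tested with layout, genotype and sex as terms, which is the same test as that of a genotype change that differs between the layouts. In that fit each paired-end library is fitted exactly, so the standard errors and p-values measure only the spread between single-end libraries of the same genotype. Levels are CPM, counts scaled to a common library size after TMM, as mean ± SD of 3 libraries.

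Gene lists were tested with limma 3.58.1 (camera, two-sided, preset correlation 0.01, log2 CPM with a prior count of 2), with fry and with an estimated correlation as alternatives. There were 46 lists with 977 genes, of which 973 matched a symbol, 4 did not and 851 passed the filter. The 45 lists with at least 3 measured genes were tested. Genes named below are the 10 largest rises and the 10 largest falls among called genes with a mean log2 CPM of at least 0 and the same sign in both layouts. Predicted genes, unnamed identifiers, pseudogenes and sex-linked genes were left out of this choice. Atp7b, Mt1 and Mt2 were added, and for each list up to 4 members with the smallest p, called or not. Other list members are named as values. Not every gene that this rule names is given in the text. For the labelled sexes, the 5 largest differences each way, Xist, the Y-linked genes and up to 4 members of each sex-biased list were named. The design, the lists, this rule and the alternatives were fixed before the data were examined, except 2 alternatives chosen after seeing the data: leaving out the 2 libraries whose sex-linked counts go against their label, and removing a trend on transcript length and GC content.

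The procedure was tested on simulated counts for 12988 genes with 200 of them changed. For genotype it recovered 13% of 2-fold and 80% of 4-fold changes, and 11 of its 104 calls were false. With no gene changed it made 5 calls. For labelled sex it recovered 14% of 2-fold and 82% of 4-fold changes, 24 of 120 calls were false, and 1 call was made with no gene changed. Alternatives were other covariates, RLE and upper-quartile scaling, no filter and a stricter one, paired-end libraries thinned to the mean single-end depth, DESeq2 1.42.0, limma-voom, the single-end libraries alone, and leaving out each library in turn. Intervals and floors given for low counts cover counting error only, since reads without molecular identifiers are not independent molecules. A floor is 3 counts over the libraries of a genotype. Figures were drawn with matplotlib 3.10.9.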

Results

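Transcripts were counted in 3 wild type and 3 Atp7b-/- liver libraries from mice at 6 weeks of age, with total counts of 5919389 to 25973968 per library. The question was which liver transcripts differ when Atp7b, the ATPase that loads copper onto ceruloplasmin and exports it into bile, is lost.

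Atp7b transcripts were lower and metallothionein transcripts higher in Atp7b-/- livers. Atp7b (ENSMUSG00000006567, chromosome 8, 21992785 to 22060305, minus strand, GRCm38) stood at 56.7 ± 30.1 CPM in wild type and 15.4 ± 3.32 CPM in Atp7b-/- livers (mean ± SD, n = 3 each), a 3.31-fold lower level. Its CPM was 25.3, 85.2 and 59.7 in wild type replicates 1 to 3 and 19.2, 13.8 and 13.3 in Atp7b-/- replicates 1 to 3. Mt2, a small protein that binds copper and zinc, rose 15.8-fold, from 38.1 ± 25.2 to 734 ± 522 CPM. Its neighbour Mt1 on chromosome 8 (94179082 to 94180327) rose 12.6-fold, from 350 ± 425 to 3980 ± 3410 CPM. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, Atp7b fell by 1.73 on the log2 scale (SE 0.30, adjusted p = 0.02), Mt2 rose by 3.98 (SE 0.36, adjusted p = 0.00101) and Mt1 by 3.66 (SE 0.59, adjusted p = 0.0337). Mt1 was 26.5 and 421 CPM in the paired-end wild type and Atp7b-/- libraries and 192 to 831 against 4320 to 7210 CPM in the single-end ones, so that the genotypes overlapped across layouts. The part of Atp7b that was targeted is not given in the sources used here, so reads outside it can remain. The Atp7b call was lost without wild type replicate 3, Atp7b-/- replicate 1 or Atp7b-/- replicate 2 (adjusted p = 0.0686, 0.0969 and 0.0664; 2.6e-10 to 1 over all alternatives). That of Mt1 was lost without wild type replicate 1, Atp7b-/- replicate 1 or Atp7b-/- replicate 3 (up to 0.214; 1.47e-11 to 1 over all alternatives).

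**Figure D1:**
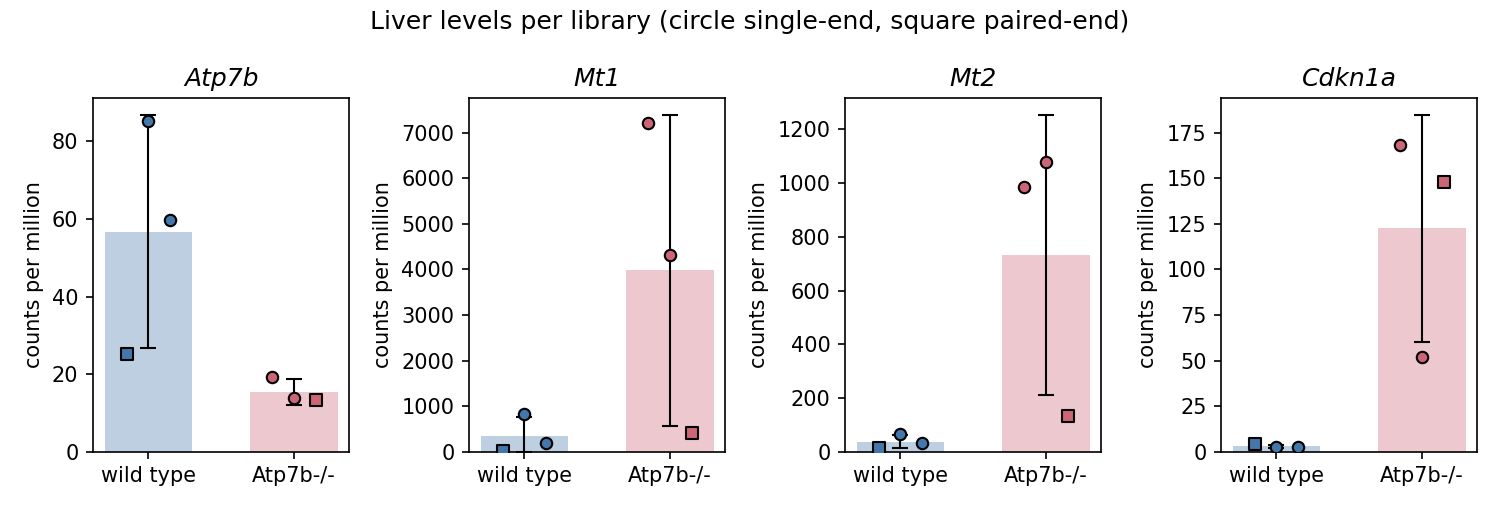
CPM of Atp7b, Mt1, Mt2 and Cdkn1a in each library (y axes, linear, from 0) by genotype; bars are means of 3 libraries, error bars 1 SD with the lower end held at 0, circles single-end and squares paired-end libraries. Atp7b is at 13.3 to 19.2 CPM in the Atp7b-/- libraries and at 25.3 to 85.2 CPM in wild type, and Cdkn1a has a mean of 3.1 CPM in wild type and 122 CPM in Atp7b-/- livers.

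Beyond Atp7b, no gene of copper handling was called, and the list did not pass the set test (camera adjusted p = 0.726). Of 21 measured copper handling genes, Atp7b fell and 20 did not pass the test, and adjusted over the list alone the count was also 1. The copper importer Slc31a1 had a log2 fold change of -0.55 (SE 0.20, adjusted p = 0.241) and the copper chaperone Atox1 one of 0.40 (SE 0.19, adjusted p = 0.38). In the list of metallothioneins and other targets of the metal-responsive factor MTF1, 2 of 7 measured genes rose, over all genes and adjusted over the list alone, and the zinc exporter Slc30a1 stood at 0.31 (adjusted p = 0.568). That list was higher in the set test (camera adjusted p = 0.0201; 0.00621 to 0.494 over the alternatives; fry 0.1). For this and every other called list the highest adjusted p was the one with an estimated correlation between genes, with which only the mitosis list was called. No member of the zinc transport list (16 measured, camera adjusted p = 0.598) or of the iron handling list (19 measured, 0.759) was called, although the hepcidin genes Hamp and Hamp2 had log2 fold changes of -0.69 and -2.78 (adjusted p = 0.173 and 0.17).

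Across all genes, 323 of 12988 (2.49%) were called, 247 higher and 76 lower in Atp7b-/- livers, and 312 of them differed at least 2-fold. The largest rises included Cdkn1a (ENSMUSG00000023067), which encodes the cell cycle inhibitor p21, the neighbouring noncoding RNA Trp53cor1, and the mitotic genes Psrc1 and Ncapg. The largest falls included Clec2h and the growth regulator Myc (ENSMUSG00000022346). Cdkn1a rose 39.8-fold, from 3.1 ± 0.849 to 122 ± 62 CPM, and Myc fell 9.53-fold, from 47.2 ± 14.9 to 5.11 ± 2.04 CPM. On the log2 scale Cdkn1a rose by 5.31 (SE 0.49, adjusted p = 0.00258) and Myc fell by 3.25 (SE 0.21, adjusted p = 0.000411). The other large rises were those of Got1l1 (6.48), Ddias (5.35), Shcbp1 (5.31), the DNA polymerase gene Polq (5.29), Trp53cor1 (5.95) and Ncapg (5.56), with adjusted p between 0.000951 and 0.00759. Their wild type means were 0.0609 CPM for Got1l1, 0.074 for Trp53cor1, 0.178 for Ncapg, 0.258 for Polq, 0.348 for Shcbp1 and 0.721 for Ddias. The sizes of these rises therefore rest on low wild type counts. Psrc1 had 289 counts in Atp7b-/- livers against 2 in wild type, a ratio of 106 (95% exact counting interval 29 to 878), and Aunip 159 against 2 (58.2, 15.9 to 485). Itln1 had 213 counts against 0 and was at least 52-fold higher in Atp7b-/- livers. Clec2h had 1 count in Atp7b-/- livers against 693 in wild type (ratio 946, 169 to 37400). The adjusted p was 0.0219 for Itln1, 0.00885 for Aunip and 0.0011 for Psrc1 and Clec2h. The other large falls were those of Epop (-5.07), Mug2 (-3.34), the structural protein gene Tchh (-3.16), the chromatin assembly factor subunit Chaf1b (-2.96), the acyl-CoA thioesterase Acot2 (-2.95), Gas1 (-2.66), Jph1 (-2.64) and the Wnt receptor Fzd8 (-2.57), with adjusted p between 0.00454 and 0.0379.

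The genotype had the same sign of change in both layouts in 322 of the 323 called genes, all but the antisense RNA Gm12473, which the choice of these genes by a fit over both layouts favours; over all genes 58.1% had the same sign. In 269 called genes the CPM ranges of the genotypes did not overlap, as in 1105 of all genes tested (8.51%). Chance would give 10% for 3 against 3 exchangeable libraries. The layouts differed in 52.8% of genes and each genotype holds both, so the 10% is no measure for these libraries. In edgeR, 545 genes had an unadjusted p under 0.05 without the layout term and 381 with labelled sex in its place. Both are below the share of 0.05 expected by chance. The number of calls was 0 in both fits. With layout, DESeq2 gave 770 and limma-voom 396. It was 126 in the single-end libraries alone (114 of them among the 323), where labelled sex follows the genotype. It was 131 without wild type replicate 1, 208 without Atp7b-/- replicate 1 and 119 without Atp7b-/- replicate 3. Of the 20 largest changes 11 kept their call when any 1 library was left out: Got1l1, Psrc1, Ncapg, Ddias, Shcbp1, Polq, Clec2h, Myc, Acot2, Gas1 and Fzd8. Cdkn1a lost its call without wild type replicate 3 (adjusted p = 0.0741; 9.63e-65 to 0.372 over all alternatives). Itln1, Trp53cor1 and Aunip lost theirs without either paired-end library (up to 0.141, 0.0817 and 0.101), and Mug2 without wild type replicate 3 or Atp7b-/- replicate 1 (up to 0.236). The call was lost for Epop in 3 of the 6 leave-outs (up to 0.0896), for Jph1 in 4 (up to 0.158), and for Tchh and Chaf1b in 5 (up to 0.197 and 0.131).

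Genes of mitosis and cytokinesis were higher in Atp7b-/- livers. Of 43 measured members 31 rose, 12 did not pass the test and none fell; adjusted over the list alone 38 rose. The median log2 fold change was 2.94, and 42 of 43 members had a positive one. Cdc20, an activator of the anaphase-promoting complex, rose 25.4-fold, from 1.55 ± 1.12 to 32.6 ± 4.39 CPM (log2 4.67, SE 0.38, adjusted p = 0.000951). The spindle checkpoint gene Mad2l1 rose 9.36-fold, the condensin genes Smc2 5.45-fold and Ncapg 47.2-fold, each with the same adjusted p. Ncapg had a wild type mean of only 0.178 CPM, so the size of its rise is uncertain. The proliferation marker Mki67 had a log2 fold change of 0.84 (SE 0.61, adjusted p = 0.595) and Ccna2 one of 1.42 (SE 0.59, adjusted p = 0.316). The list was called by camera (adjusted p = 8.53e-41), by fry (0.00139) and with an estimated correlation (0.0225), the highest of its alternatives (1.2e-67 to 0.0225). The number of called members was 19 in the single-end libraries alone, 19 without wild type replicate 1, 18 without Atp7b-/- replicate 3, and 0 without the layout term.

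Genes of DNA replication and the G1/S transition went both ways. Of 34 measured members, 2 rose, 1 fell and 31 did not pass the test; adjusted over the list alone 3 rose, among them the clamp loader gene Rfc5, and 1 fell (Chaf1b). Chaf1a, which encodes a subunit of a chromatin assembly factor, rose 7.86-fold (log2 2.97, SE 0.27, adjusted p = 0.000951). Chaf1b, which encodes another subunit of the same factor, fell by 2.96 on the log2 scale (SE 0.51, adjusted p = 0.0175). The replicative helicase gene Mcm2 had a log2 fold change of -0.89 (adjusted p = 0.432) and the sliding clamp gene Pcna one of -0.66 (adjusted p = 0.558). The median was -0.03 and the mean 0.12, which differ in sign, and camera did not call the list (direction up, adjusted p = 0.417).

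Targets of the tumour suppressor p53 rose. Of 23 measured members 10 rose and none fell, and adjusted over the list alone 17 rose. Besides Cdkn1a, the apoptosis-enhancing nuclease gene Aen rose 3.58-fold (log2 1.84, SE 0.20, adjusted p = 0.00184), the cyclin G gene Ccng1 4.41-fold (log2 2.14, SE 0.25, adjusted p = 0.00247) and the antiproliferative gene Btg2 3.3-fold (log2 1.72, SE 0.24, adjusted p = 0.006), the last of these called only with both paired-end libraries (up to 0.0722 without them). Mdm2, which encodes the ubiquitin ligase of p53, rose by 1.63 and Bax by 1.35 (adjusted p = 0.00605 and 0.00745). The list's median was 1.43 (camera adjusted p = 3.37e-11; 3.22e-16 to 0.431 over the alternatives; fry 0.0442). Called members numbered 5 in the single-end libraries alone, 5 without either paired-end library, and 0 without the layout term.

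Genes of conjugation and targets of the oxidative stress factor NRF2 rose as a list. Of 24 measured members 4 rose, none fell and 20 did not pass the test; adjusted over the list alone 9 rose and Ugt1a6a fell. The glutathione transferase gene Gsta1 rose 13.1-fold, from 0.545 ± 0.257 to 6.97 ± 6.09 CPM, Gsta2 2.9-fold and Gstm4 2.36-fold, and the sulfiredoxin gene Srxn1 rose 2.14-fold (adjusted p = 0.00885, 0.00885, 0.0179 and 0.0204). Nqo1 and Hmox1 had log2 fold changes of 0.64 and 0.57 (adjusted p = 0.417 and 0.369). The list's median was 0.50 (camera adjusted p = 0.000123; 4.19e-06 to 0.356 over the alternatives; fry 0.0232). None of these 4 genes was called without either paired-end library or in the single-end libraries alone (adjusted p there 0.0881 to 0.143), and Gstm4 and Srxn1 were also lost without other libraries. The antioxidant enzyme list (16 measured, none called, camera adjusted p = 0.726) did not pass. Among 22 measured genes of phase I metabolism the oxidase gene Aox1 rose by 1.46 (SE 0.30, adjusted p = 0.0449) and Cyp2c29 fell by 1.10 (SE 0.24, adjusted p = 0.0496). These calls were lost in 4 and 5 of the 6 leave-outs (up to 0.129 and 0.228). Adjusted over the list alone, Aox1, Cyp2a5, Cyp2b10 and Ephx1 were higher and Cyp2c29 and Por lower (camera adjusted p = 0.86).

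By camera, the lists of fatty acid oxidation, fatty acid synthesis and sterol uptake were lower in Atp7b-/- livers, and by fry only the last of these. Of 24 measured genes of fatty acid oxidation, the thioesterase gene Acot1 fell 5.27-fold (log2 -2.40, SE 0.35, adjusted p = 0.00805) and 23 did not pass the test. Adjusted over the list alone, Pdk4 was higher and Acot1 lower. In all, 21 of 24 changes were negative (median -0.28, camera adjusted p = 0.00348; 0.000934 to 0.417 over the alternatives; fry 0.0571). The lipid-binding protein gene Fabp1 had a log2 fold change of -0.96 (adjusted p = 0.22) and the kinase gene Pdk4, which restrains pyruvate oxidation, one of 1.69 (adjusted p = 0.0818). In the fatty acid synthesis list none of 19 members was called over all genes, and 4 fell adjusted over the list alone. Its leading members were the transcription factor gene Srebf1 (479 CPM in wild type and 214 CPM in Atp7b-/- livers, adjusted p = 0.0997), Fads2 (log2 fold change -0.82, adjusted p = 0.0998), Pklr (-1.02, 0.104) and Fasn (-0.76, 0.143), and the list was lower by camera (adjusted p = 0.03; 0.00227 to 0.628 over the alternatives; fry 0.297). Among 15 genes of sterol uptake and SREBP2 regulation 1 rose and 4 fell adjusted over the list alone. Among these were the sterol sensor partner Insig2 (log2 fold change 1.20, adjusted p = 0.187 over all genes), Mylip (-0.71, 0.133) and Scap (-0.64, 0.135). The list was lower (camera adjusted p = 0.03; 0.0175 to 0.477 over the alternatives; fry 0.0442). Cholesterol biosynthesis was not called (21 measured, camera adjusted p = 0.121). In bile acid and canalicular transport (14 measured, camera adjusted p = 0.486) the bile salt importer gene Slc10a1 fell 2.48-fold, from 1020 ± 281 to 425 ± 158 CPM (log2 -1.31, SE 0.25, adjusted p = 0.0276), a call lost in 4 of the 6 leave-outs (up to 0.184). The bile acid synthesis list did not pass (13 measured, camera adjusted p = 0.945, with a median of 0.05 against a test direction of down).

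Further lists were called by camera, most of them with few or no called genes. All 22 measured proteasome subunits had positive changes, with a median of 0.36, none called over all genes and only Psmd14 adjusted over the list alone (camera adjusted p = 0.000167; 2.3e-07 to 0.723 over the alternatives; fry 0.314), where Psmd14 stood at 0.97 (adjusted p = 0.0672). The circadian clock list was lower (18 measured, median -0.84, camera adjusted p = 0.0021; 2.48e-05 to 0.494 over the alternatives; fry 0.178). In it Hlf fell by 0.92 (SE 0.18, adjusted p = 0.0323), a call lost in each of the 6 leave-outs (0.0569 to 0.196), and Arntl and Per3 had log2 fold changes of 3.38 and -2.28 (adjusted p = 0.302 and 0.396). The time of day of tissue collection is not given in the sources used here. Endothelial markers were lower (17 measured, none called, median -0.33, camera adjusted p = 0.00778; 0.00178 to 0.723 over the alternatives; fry 0.297), among them Flt4 at -0.54 and Egfl7 at -0.49 (adjusted p = 0.279 and 0.299). Nuclear receptors and liver transcription factors were lower (31 measured, none called, median -0.14, camera adjusted p = 0.0396; 0.0132 to 0.494 over the alternatives; fry 0.297), led by Foxa1 at -1.09 and Foxa3 at -0.87 (adjusted p = 0.117 and 0.151). Only 3 of 19 pancreatic acinar genes passed the filter, and the list was higher (median 1.39, camera adjusted p = 0.00286; 5.38e-05 to 0.417 over the alternatives; fry 0.0137). Of these the trypsin inhibitor gene Spink1 was called, with 65 counts in Atp7b-/- livers against 1 in wild type (ratio 47.6, 8.25 to 1910, adjusted p = 0.0137), a call lost without either paired-end library (up to 0.192). The female-biased liver genes were lower (17 measured, none called, median -2.95, camera adjusted p = 0.0342; 2.34e-10 to 0.82 over the alternatives; fry 0.647), while wild type had 2 libraries labelled female and Atp7b-/- had 1. The labels may understate this imbalance. Xist, an RNA of females, was at most 0.702 CPM in the Atp7b-/- libraries, against 1.01, 371 and 17.4 CPM in wild type replicates 1 to 3.

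**Figure D2:**
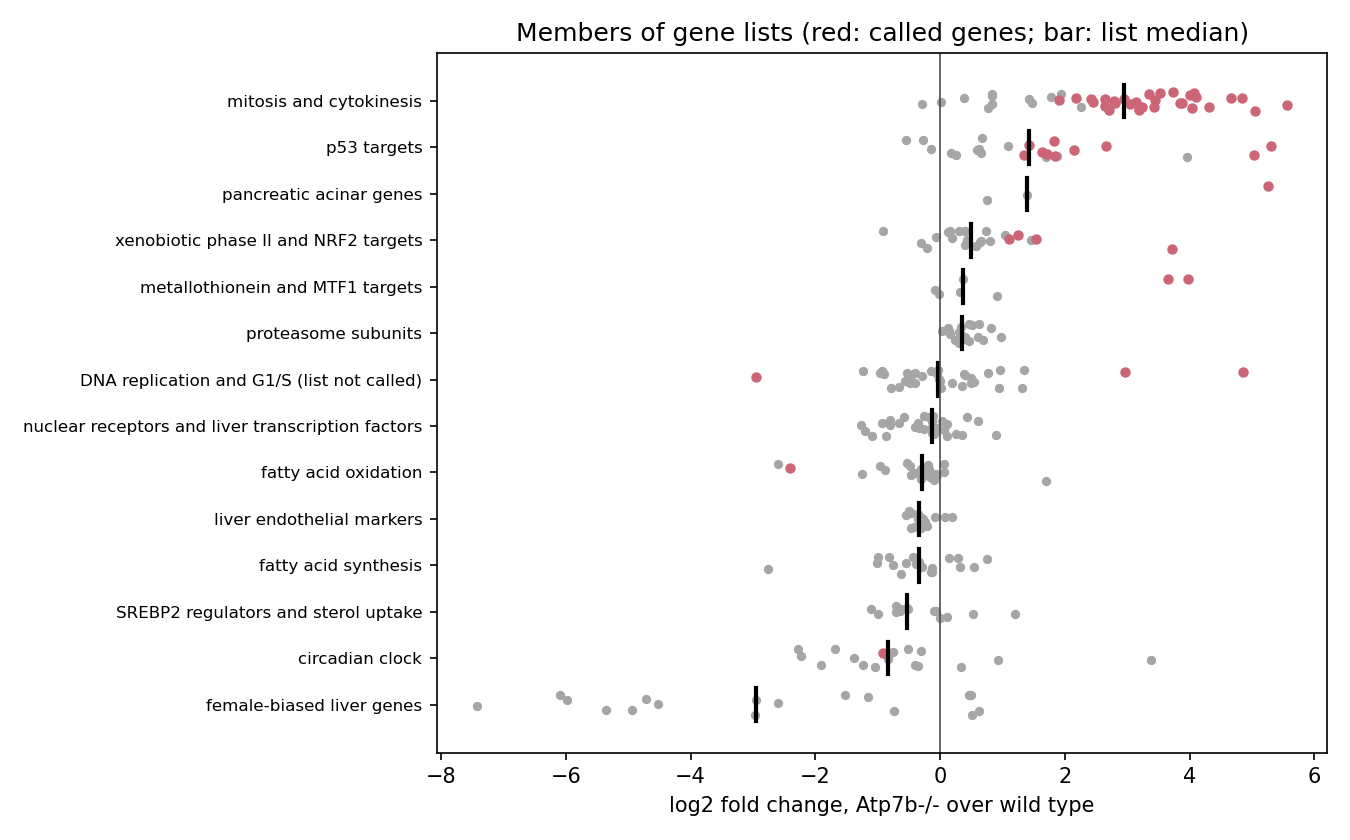
Log2 fold change of Atp7b-/- over wild type (x axis) for each measured member of the 13 lists called by camera and of the DNA replication list (y axis); red points are called genes, the vertical bar is the list median. Members of the mitosis list have a median of 2.94 and those of the DNA replication list a median of -0.03.

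The other 32 tested lists were not called (camera adjusted p = 0.121 to 0.999). Camera asks for a shift in 1 direction. In fry's mixed test, which takes changes either way, some of these lists passed. Among them were periportal genes (adjusted p = 0.000904), chemokines and cytokines (0.00103) and DNA replication genes (0.0011). Others did not, such as ribosomal proteins (0.815) and macrophage and Kupffer cell genes (0.846). Immune and inflammatory lists showed no called gene except Il6ra, the receptor for interleukin 6, which fell by 1.40 (SE 0.23, adjusted p = 0.0151) in the acute phase list (23 measured, adjusted p of the list 0.121) and was not called without either paired-end library (up to 0.0948). The lists of interferon response (26 measured, 0.598), macrophages and Kupffer cells (20, 0.6), monocytes and neutrophils (3, 0.999), lymphocytes (7, 0.6), and chemokines and cytokines (10, 0.634, with a median of -0.15 against a direction of up) did not pass. The same was true of those of the unfolded protein response (22 measured, 0.296) and heat shock (16, 0.546), where Asns had a log2 fold change of 3.46 (adjusted p = 0.215). Stellate cell and fibrosis genes (27 measured, 0.167) and cholangiocyte and progenitor markers (12, 0.135) held no called gene; the intermediate filament gene Des stood at 97.5 CPM in wild type replicate 1 and at 3.62 to 10.9 CPM elsewhere. In the list of periportal genes (13 measured, 0.278) the immunoglobulin receptor gene Pigr fell by 1.28 (SE 0.21, adjusted p = 0.0128) and the cadherin gene Cdh1 rose by 1.13 (SE 0.21, adjusted p = 0.0219), each a call lost in 4 of the 6 leave-outs (up to 0.0938 and 0.0784), and the pericentral list (13, 0.256) held no call. The lists of hepatocyte secreted proteins (23, 0.288), gluconeogenesis and glycogen (17, 0.201), and urea cycle and amino acid catabolism (23, 0.23) also held none; the albumin gene Alb had a log2 fold change of -0.72 (adjusted p = 0.256). The same held for oxidative phosphorylation (38, 0.917, with a median of 0.04 against a direction of down), mitochondrially encoded genes (7, 0.155), ribosomal proteins (44, 0.999), splicing factors (31, 0.486), erythroid genes (6, 0.121), adipose and muscle genes (4, 0.155), male-biased genes (22, 0.121) and Y-linked genes (4, 0.121). Adjusted over the list alone, Apcs (acute phase), Mx2 (interferon) and Cd4 (lymphocytes) were higher and Il6ra, Socs3 (acute phase) and Car3 (adipose and muscle) lower. The X-inactivation list holds only Xist and was not tested. The 33 lists without a called gene have 577 measured genes, of which edgeR called 0 with 81 at an unadjusted p under 0.05, DESeq2 called 33 and limma-voom 2.

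Genotype changes measured in the single-end libraries (2 against 2) and in the paired-end libraries (1 against 1) went the same way for most of the strongly changed genes. Of the 140 genes called in the single-end libraries over the same gene set, 134 (95.7%) had the same sign in the paired-end pair, with a median paired-end log2 fold change of 3.01 for the 114 higher genes and -1.22 for the 26 lower ones. Myc changed by -3.12 and -3.39 and Cdkn1a by 5.09 and 5.14 in the single-end and paired-end libraries. Over all 12988 genes, which are not independent replicates, Pearson's r was 0.457 and Spearman's rho 0.279, and 58.1% of genes had the same sign. The layouts themselves differed in 6864 genes (52.8%), 3531 higher and 3333 lower in the paired-end libraries.

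**Figure D3:**
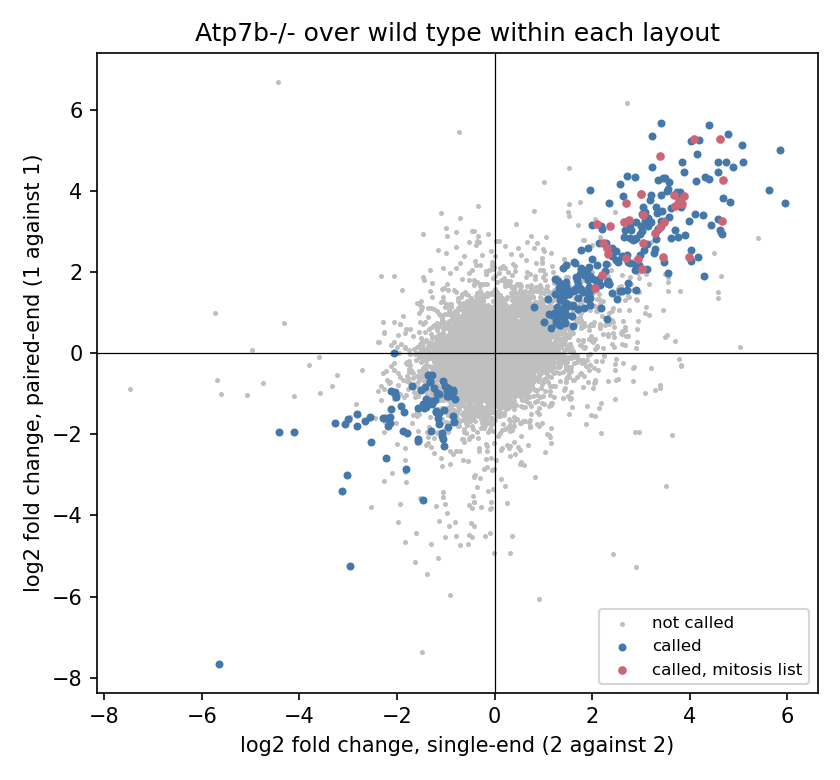
Log2 fold change of Atp7b-/- over wild type in the single-end libraries (x axis, 2 against 2) and in the paired-end libraries (y axis, 1 against 1) for each tested gene. Pearson's r across the 12988 genes is 0.457, and 322 of the 323 called genes have the same sign on both axes.

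Between libraries labelled male and female 2 genes were called. The male-biased serine protease inhibitor gene Serpina1e (chromosome 12, 103946931 to 103958975) was higher in libraries labelled male by 3.49 on the log2 scale (SE 0.27, adjusted p = 0.0181), with 7720 CPM in wild type replicate 1 and 113 to 269 CPM in the other 5. Star (chromosome 8, 25806555 to 25815982), whose protein carries cholesterol into mitochondria for steroid synthesis, was lower by 3.17 (SE 0.24, adjusted p = 0.0181), with 141 CPM in Atp7b-/- replicate 3 and 1.26 to 3.06 CPM elsewhere. Each thus rests on 1 paired-end library. The SE and adjusted p do not measure the spread of such libraries, because this fit takes each paired-end library exactly. The major urinary protein gene Mup7 likewise stood at 4540 CPM in wild type replicate 1 and at most at 118 CPM elsewhere, with a log2 difference of 3.59 (adjusted p = 0.987). Unadjusted, 594 genes had a p under 0.05, which is below the share of 0.05 expected by chance. The number of calls was 70 in DESeq2, 1 in limma-voom, 141 without wild type replicate 3 and 46 without wild type replicate 2. It was 0 without either single-end Atp7b-/- library (459 and 446 genes at an unadjusted p under 0.05).

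The sex-linked transcripts went against the label in 2 libraries. Xist, the RNA that silences one X chromosome in females, stood at 371 CPM in wild type replicate 2, 17.4 CPM in wild type replicate 3 and 0.482 CPM in Atp7b-/- replicate 3, all labelled female, and at 0.117 to 1.01 CPM in the libraries labelled male. The summed level of the 6 Y-linked genes was 0.68, 59.5 and 295 CPM in the same 3 libraries labelled female and 342, 86.5 and 83.8 CPM in wild type replicate 1 and Atp7b-/- replicates 1 and 2. Of the Y-linked genes Ddx3y stood at 0.34 CPM in wild type replicate 2, 28 CPM in wild type replicate 3 and 126 CPM in Atp7b-/- replicate 3. The libraries are called by their labels throughout, and differences between the labelled sexes are differences between labels. By Xist and the Y-linked genes no Atp7b-/- library resembled wild type replicate 2. Sex may therefore follow the genotype more closely than the labels say.

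**Figure D4:**
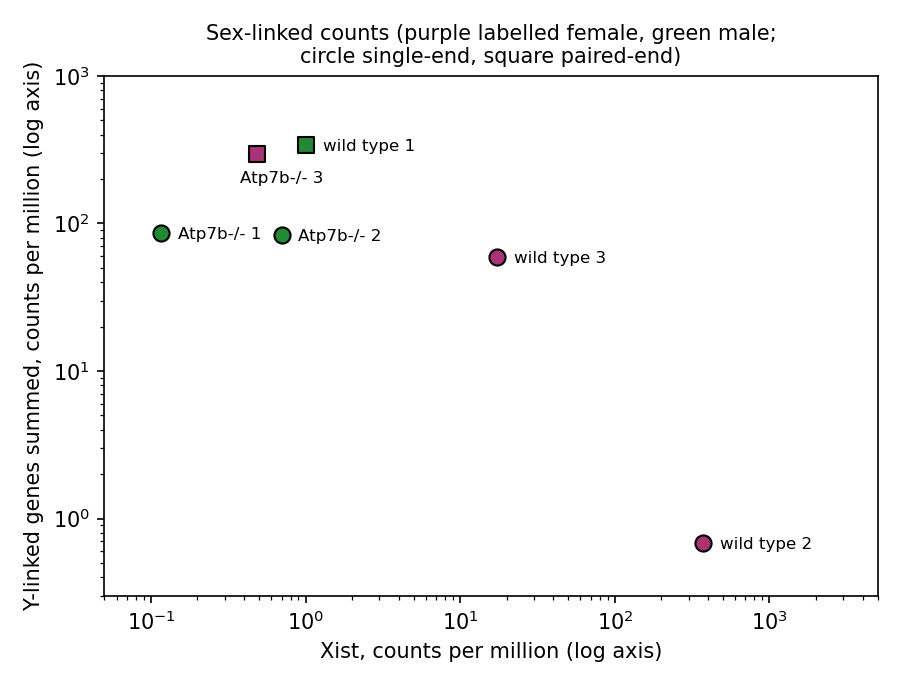
Xist (x axis, CPM, log scale) against the summed Y-linked genes (y axis, CPM, log scale) in each library; purple marks libraries labelled female, green those labelled male, circles single-end and squares paired-end. Only wild type replicate 2 combines a high Xist level (371 CPM) with a low Y-linked level (0.68 CPM).

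By labelled sex 9 lists were called by camera and 0 of 45 with an estimated correlation (adjusted p from 0.694). The male-biased liver genes were higher in libraries labelled male (22 measured, 21 positive, median 0.88, Serpina1e called and also Mup11 adjusted over the list alone, camera adjusted p = 2.67e-07; 3.37e-29 to 0.694 over the alternatives; fry 0.677). Among them Mup11 and Nudt7 had log2 differences of 2.48 and 0.74 (adjusted p = 0.388 and 0.987). The female-biased genes were lower (17 measured, none called over all genes and Cyp4a14 adjusted over the list alone, median -1.76, camera adjusted p = 0.00303; 1.51e-11 to 0.706 over the alternatives; fry 0.826). Cyp4a14 and Hao2 had log2 differences of -1.76 and -7.35 (adjusted p = 0.253 and 0.987), and Hao2 stood at 38.8 CPM in wild type replicate 2, 22.8 CPM in Atp7b-/- replicate 3 and at most 1.11 CPM elsewhere. Stellate cell and fibrosis genes (camera adjusted p = 1.1e-05), periportal genes (0.000981), urea cycle genes (0.00303), gluconeogenesis genes (0.0121), mitochondrially encoded genes (0.0121), proteasome subunits (0.019) and clock genes (0.0249) were higher in libraries labelled male, and each reached 0.694 or 0.706 with an estimated correlation and 0.0765 to 0.722 by fry. Adjusted over the list alone, 3 stellate cell genes that smooth muscle also expresses (Acta2, Tagln and Des) and the glucose-6-phosphatase gene G6pc were higher, and 6 clock genes were higher and 2 lower. Acta2, Tagln and Des were high in wild type replicate 1 alone (146, 147 and 97.5 CPM, against at most 6.67, 8.84 and 10.9 CPM elsewhere). Of the 137 genes in these lists and the female-biased list, edgeR called 0 over all genes with 29 at an unadjusted p under 0.05, DESeq2 14 and limma-voom 0.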

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

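The tests on the sex-linked counts were chosen only after those counts were seen, and the tests on other tissues after the pattern was seen but before the values of the genes they measure were seen. Y-linked transcripts stood out because they appear in 2 of the 3 libraries labelled female, at 59.5 CPM in wild type replicate 3 and 295 CPM in Atp7b-/- replicate 3, against 0.68 CPM in wild type replicate 2. Reads shared with X-linked homologs would also reach wild type replicate 2, and the other libraries labelled female had at least 87.5 times its Y-linked level, which argues against this explanation. For Atp7b-/- replicate 3 a wrong sex label stays open: its Y-linked level was 0.863 of that of the paired-end library labelled male, with Xist at 0.482 CPM. Other genes go both ways: the female-biased gene Hao2 goes with the label (22.8 CPM, against at most 0.281 CPM in the libraries labelled male), Cyp4a14 goes against it (4.61 CPM, against 4.89 CPM in the paired-end library labelled male), and Serpina1e and Mup7 are far below wild type replicate 1 in it (115 against 7720 and 118 against 4540 CPM) but also in the single-end libraries labelled male. For wild type replicate 3 RNA of both sexes stays open, since its Xist level was 24.8 times that of the highest single-end library labelled male, and no biological explanation was tested for either library.

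Genes of other tissues stood out in the paired-end libraries. Only 3 of 19 adrenal genes and 2 of 15 squamous epithelial genes passed the expression filter, so the comparisons use few of these. They do use the adrenal gene Star and the smooth muscle genes Acta2, Tagln and Des, which are among the results by labelled sex. Adrenal genes summed to 1010 CPM in Atp7b-/- replicate 3 and at most 8.14 CPM elsewhere, with Hsd3b1 at 196, Star at 141, Cyp11a1 at 139 and the chromaffin cell gene Chgb at 108 CPM. Genes of stratified squamous epithelium summed to 339 CPM in wild type replicate 1 and at most 10.4 CPM elsewhere, with Krt13 at 79.7 and Krt4 at 66.3 CPM, beside the smooth muscle genes Tagln and Acta2 at 147 and 146 CPM. RNA of these tissues fits: for 8 further genes of each tissue the median ratio to the highest other library was 10.5 for adrenal gland (1.82 to 99.1, 4 of 8 above 10) and 13 for squamous epithelium (0.54 to 139, 5 of 8 above 10), the adrenal value only just above the limit of 10 set for the test. Whether it came with the tissue or was added later was not tested, nor was a biological explanation, and the single-end libraries alone gave 126 called genes.

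The genotype change of Star differed between the layouts, at -0.73 in the single-end and 5.47 in the paired-end libraries, in the same test as that of labelled sex (log2 difference between labelled sexes -3.17). The genotype change of Serpina1e differed between the layouts in that test, at 0.92 in the single-end and -6.07 in the paired-end libraries (log2 difference between labelled sexes 3.49). The paired-end changes compare 1 library against 1, and the test does not measure their spread.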

How the results depend on the processing

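All alternatives were chosen before the data were examined except the length and GC correction and the omission of the 2 libraries with discordant sex-linked counts, chosen after seeing the data. Without covariates 0 genes were called, with Atp7b at -1.88 (adjusted p = 0.514), and with sex alone 0, with Atp7b at -1.53 (adjusted p = 1; 2.6e-10 to 1 over the alternatives of Atp7b); mitosis, p53 and NRF2 genes called higher were then 0, 0 and 0. Calls numbered 1116 with no filter, 770 in DESeq2 (NRF2 genes 7 and 8) and 126 in the single-end libraries alone (mitosis 19, p53 5, NRF2 0), the last having fewer samples, and NRF2 genes 2 with layout and sex. They stayed at 277 with layout and sex (226 shared), 324 with RLE, 321 with upper-quartile scaling, 311 with a stricter filter, 306 thinned, 396 in limma-voom and 325 with the length and GC trend removed. Without the discordant libraries the fit gave 307 calls, only 159 of them shared: it sets wild type replicate 2 alone, labelled female, against Atp7b-/- replicates 1 and 2, labelled male, so it is confounded with sex and no check of the result. Leaving out 1 library gave 119 to 323 calls, 5 to 17 lists, 18 to 29 mitosis genes, 5 to 12 p53 targets, 0 to 5 NRF2 genes and an Atp7b change of -2.13 to -1.45. A lone library of a layout is then fitted exactly and adds no spread. The same holds for both paired-end libraries in the fit with layout and sex. That fit takes sex from the labels, which the sex-linked counts of 2 libraries go against, so it does not show that sex is accounted for. Lists called were 1 with an estimated correlation and 5 by fry. Between labelled sexes, calls were 159 with no filter, 70 in DESeq2, 1 in limma-voom, 0 with genotype alone (49 genes at an unadjusted p under 0.05 in edgeR), 0 without covariates (54) and 0 to 141 leaving out 1 library; lists were 0 with an estimated correlation and 4 to 13 leaving out 1 library. The correlation of the layouts was 0.316 above a mean log2 CPM of 5 and 0.378 to 0.469 leaving out 1 library. Of the named genes 13 turned sign somewhere, none of them called: Ccr2 0.0151 and Cidec -0.125 without covariates; Cidec -0.197 with sex alone and -0.196 with layout and sex; Ccr2 0.0233 and Csf3r 0.0435 with upper-quartile scaling; Csf3r 0.0243 with no filter, 0.0868 thinned and 0.0233 with the length and GC trend removed. In limma-voom Ccr2 was at 0.00389 and Cidec at -0.283, and in the single-end libraries Plac8 was at -0.0186, Ighm 0.222 and Car2 -0.146. Without the discordant libraries Glrx was at 0.176, Plac8 -0.518, Cd22 -0.0268, Ighm 0.205, Jchain 0.377, Car2 -0.559, Rplp1 0.255, Mup11 1.33 and Mup12 2.25. Leaving out 1 library gave Plac8 -0.0601 to 0.739, Ighm -0.768 to 0.229, Jchain -1.55 to 0.423, Car2 -0.146 to 0.985, Mup11 -3.49 to 0.436, Ccr2 -0.376 to 0.217, Csf3r -0.244 to 0.175, Cidec -0.212 to 0.706 and Ddx3y -0.0142 to 2.25. Except for fewer samples, the cause was not tested. Of the 44 called genes that the naming rule chose, 20 kept their call whichever library was left out. The simulation recovered 13% of 2-fold changes, so changes of that size were mostly beyond this design. No paired analysis was possible because the replicate numbers only follow the order of deposition.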

Other observations

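Of the tests below, those on sex and on immune cells and the comparison of mitosis with DNA replication were chosen only after the result was seen. Several genes outside the lists also changed in Atp7b-/- livers, and those named here were chosen after their values were seen. Cplane1, a gene of ciliogenesis, rose from 11 to 371 CPM (log2 5.07, SE 0.33, adjusted p = 0.000411), the glutamate receptor gene Gria3 from 2.86 to 36.1 CPM (adjusted p = 0.000411) and the sugar phosphate transporter gene Slc37a2 from 3.7 to 34.1 CPM (adjusted p = 0.000715). The lipoprotein lipase gene Lpl rose from 40.1 to 151 CPM (adjusted p = 0.00449). The stress cytokine gene Gdf15 rose from 3.98 to 53.8 CPM (adjusted p = 0.0276), a call lost without wild type replicate 2, wild type replicate 3 or Atp7b-/- replicate 1 (up to 0.224).

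Other genes chosen after their values were seen fell. The deiodinase gene Dio1 fell from 103 to 28.6 CPM (log2 -1.80, adjusted p = 0.00466; not called without either paired-end library), Igfals, which encodes a carrier of insulin-like growth factors, from 257 to 87.4 CPM (adjusted p = 0.0219; not called without Atp7b-/- replicate 1 or 2) and Socs2 from 31.1 to 7.3 CPM (adjusted p = 0.0161; lost in 4 of the 6 leave-outs). The cell cycle genes E2f8 and Cdk2 fell from 11.1 to 2.85 and from 12.1 to 4.05 CPM (adjusted p = 0.00955 and 0.0169), the latter call lost in 3 of the 6 leave-outs (up to 0.157).

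The rise of mitosis genes was weighed against technical and cellular explanations. With a trend on transcript length and GC content removed, the list median was 2.86 (interquartile range 1.91 to 3.72), so that trend is not the whole cause. A sex difference would turn the change around in the paired-end libraries if their labels hold. It would leave none there if their Y-linked levels (342 and 295 CPM) make both male. Yet the list median was 2.75 in the single-end and 2.72 in the paired-end libraries, with 42 of 43 genes positive in each. In the single-end libraries labelled sex follows the genotype, so only the paired-end value argues against a sex difference. That value compares 1 library against 1. Both held transcripts of other tissues, whose part in the change was not tested. For more immune cells in the Atp7b-/- livers the data cannot tell: the median change of the 30 measured genes of the 3 immune cell lists was 0.0227 (95% bootstrap interval -0.0423 to 0.125), but they go both ways, only 7 of 23 lymphocyte and 3 of 16 monocyte and neutrophil genes were measured, and Cd4 (log2 1.51) was higher adjusted over its list. The mitosis genes are low in wild type (Cdc20 at 1.55 CPM), so a small share of dividing cells of any type could raise them, and an effect of the genotype also stays open.

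A hypothesis of this re-analysis was that transcripts of mitosis rise without those of S phase. The difference between the medians of the mitosis and the DNA replication lists was 2.97 over all libraries, 2.7 in the single-end and 2.68 in the paired-end libraries (permutation p = 1e-05, the smallest that 100000 permutations allow, with genes that are not independent of each other). The hypothesis was made from these same values, so they cannot decide it, and counts of transcripts could differ in this way without a change in the number of cells in each phase.

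Near Atp7b, strain variants carried along with the targeted allele could yield called genes. Within 20 Mb of it 4 of 175 tested genes were called (2.29%: Shcbp1, Mcph1, Ckap2 and Got1l1), against 318 of 12812 elsewhere (2.48%), an odds ratio of 0.919 (95% interval 0.246 to 2.42; one-sided Fisher p = 0.634), so the data cannot tell. Among the 10 ways to split the 6 libraries in equal groups, 1 gave as many calls as the genotypes, the true one (323, against at most 3 for the others), and with 10 splits a share under 0.05 cannot be reached. The other splits mix the genotypes, so a genotype difference adds to their spread and keeps their calls low. They give no number of calls expected by chance. For labelled sex 4 of 9 estimable splits gave at least the 2 calls of the true one, and the highest other split, with wild type replicates 1 and 2 and Atp7b-/- replicate 3 in one group, gave 35.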
